A study of Caenorhabditis elegans with 4 samples.

How the data were processed

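The series holds 4 libraries from one strain, 2 of FOS-1::GFP chromatin immunoprecipitation and 2 of input DNA, from fed L1 hermaphrodites. The libraries were grouped by the labels into ChIP and input, with the replicate numbers the labels give. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. Read counts per library were taken from the deposited sample table, in which each library stands on 2 lines with equal values. Those counts are whole numbers of reads, not normalized, and reads mapped to several places are listed as 0. The reads were 36 bp long, per the same table. The aligner is not given in the sources used here.

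Binding regions came from 3 deposited peak lists that name PeakSeq as their caller, per the file headers and source columns, with no version given in the sources used here. The authors made the combined list from the merged ChIP alignments of both replicates against merged input, per the deposited sample table, and called each replicate list on 1 ChIP library. Whether a replicate was set against its own input or the merged input is not stated. Each peak has a q value, as deposited by the authors, and all were 0.01 or lower. The q values were used only to rank, describe or filter peaks within a list. The reads were aligned to the older WS180 build per the deposited sample table, and the peaks were carried over to WS220 per the file headers, which name 4, 3 and 2 peaks of the combined, replicate 1 and replicate 2 lists whose internal structure changed in that step. These peaks were kept. ChIP against input is thus the authors' own comparison, and no read-level signal was used here.

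Peaks were compared by overlap of at least 1 bp. The share of replicate 2 peaks overlapping replicate 1 was set against 10000 random placements of each interval on its own chromosome at its own width, one-sided. The strength of shared and unshared peaks was compared by a permutation test of the difference in median −log10 q with 100000 resamples. Shares of peaks on X and in the central part of autosomes (midpoint between 33.3% and 66.7% of the length) were tested by two-sided exact binomial tests, with exact (Clopper-Pearson) 95% intervals, and a threshold of 0.05 was used throughout. The tests had been planned with chromosome lengths from a reference; none of the build was at hand, and the end of the last peak on each chromosome over the 3 lists was used in place of its length. This leaves out any peak-free end. The regions named are the 20 combined peaks with the lowest q. These choices, except the substitute for the chromosome lengths, were made before the data were examined.

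Several comparisons were added after the data were seen. Among these are the tests of single chromosomes other than X, the share of X among the 100 strongest peaks, the spacing of the strongest X peaks, the gaps between neighbouring peaks, the widest combined peak, and combined peaks without a replicate counterpart on chromosomes I and V, tested with a Mantel-Haenszel odds ratio over 10 classes of q and 1000 permutations within classes and counted in 2-Mb segments, with replicate peaks lacking a combined peak compared by Fisher's exact test. Alternatives changed the overlap rule (at least 50% of the smaller interval, or midpoints within 200 bp), used the 50% of peaks with the lowest q, one replicate list alone, or only peaks found in both replicates, left out peaks narrower than a read, or joined peaks no more than 2000 bp apart.

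The overlap, permutation and odds ratio code was tested on simulated data. With 600 of 998 intervals copied from the other list, 611 overlaps were found, the excess being chance overlaps. Of 60 lists simulated on chromosomes I and II and set against the same unrelated list, 3 gave a placement p of 0.05 or less. Of 100 unshifted pairs of samples, 2 gave a permutation p of 0.05 or less. For a true odds ratio of 4 over 6095 simulated peaks the estimate was 4.39, and for a true odds ratio of 1 it was 1.00. The simulated intervals did not cluster, and the groups of the odds ratio were drawn peak by peak. These checks therefore do not cover dependence between neighbouring peaks.

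Peaks were not assigned to genes, and motifs were not searched, because the only gene table at hand is of the WBcel235 assembly, which is not the build of the peaks, and no genome sequence was used here. The planned promoter share, the 23 gene lists, the non-coding RNA genes, the AP-1 and other motifs, the values for fos-1, jun-1 and unc-119, and the peaks around the transgene's genes were therefore not analysed here. That table was used only for the chromosome on which fos-1 lies. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.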

Results

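The data were made to map where FOS-1 bound DNA in fed first-stage (L1) larvae of Caenorhabditis elegans. FOS-1 is the worm member of the Fos family of bZIP transcription factors, best known for its part in the invasion of the anchor cell during vulval development. The animals were hermaphrodites of one strain that carried a fos-1 transgene fused to green fluorescent protein (GFP), integrated after bombardment together with an unc-119 rescue gene. They were grown at 20 °C and fixed in 2% formaldehyde, and chromatin was precipitated with an antibody against GFP. There were 2 ChIP libraries and 2 input DNA libraries, the input being chromatin that had not been precipitated. The ChIP libraries held 6307945 reads (replicate 1) and 6005290 reads (replicate 2), of which 3763795 and 2961912 mapped to a single place. The unique share was 59.7% (exact 95% interval 59.6 to 59.7) in ChIP replicate 1 and 49.3% (49.3 to 49.4) in ChIP replicate 2. The input libraries held 4425317 and 4542354 reads, with 62.4% and 61.6% mapped to a single place. ChIP replicate 2 therefore had both the lower unique share and 1.27-fold fewer usable reads than ChIP replicate 1. These intervals cover counting error only. All positions are in the WormBase WS220 build, in which the deposited peak lists are given.

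The first question was how many regions were called for FOS-1::GFP and how large they were. The list called on the merged ChIP reads (the combined list) held 6095 peaks, with a median width of 315 bp (quartiles 200 and 439), and covered 2.29 Mb, or 2.28% of the length spanned by peaks on the 6 nuclear chromosomes. Replicate 1 alone gave 4032 peaks (median width 320 bp, 1.51 Mb covered) and replicate 2 alone gave 1987 (median width 315 bp, 0.725 Mb covered). Replicate 1 thus had 2.03-fold more peaks than replicate 2. Widths ran from 1 bp upwards, and 327 combined peaks (5.37%) were narrower than the 36-bp reads. Replicate 2 had the fewer usable reads and the shorter list, and a region missing from a list was not called there, which does not show that it was unbound.

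The same regions were called in both replicates for most of the shorter list. Of the 1987 peaks of replicate 2, 1810 (91.1%, exact 95% interval 89.8 to 92.3) overlapped a replicate 1 peak by at least 1 bp. Randomly placed intervals of the same widths on the same chromosomes overlapped on average for 3.20% of peaks and never for more than 4.93% (permutation p = 0.0001, one-sided, the smallest that 10000 placements can give), so the overlap was 28.5-fold above placement. In the other direction, 1788 of the 4032 replicate 1 peaks (44.3%) overlapped a replicate 2 peak. Taking 1987 peaks with the lowest q from each replicate gave an overlap of 73.9%. The only control was input DNA, so overlap of calls does not by itself show that FOS-1 bound there.

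Regions shared by the replicates were the stronger ones. Within the replicate 1 list, the 1788 shared peaks had a median q of 5.27e-07 and the 2244 unshared peaks a median q of 0.00182, a difference of 3.54 in median −log10 q (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). Within the replicate 2 list, the corresponding medians were 0.000251 for 1810 shared peaks and 0.00556 for 177 unshared peaks. Of the combined peaks, 1776 (29.1%) overlapped peaks of both replicates, 1993 (32.7%) of replicate 1 only, 146 (2.40%) of replicate 2 only and 2180 (35.8%) of neither. The peaks found in both replicates were the widest of these classes by median, at 445 bp, with a median q of 1.02e-11, while those found in neither had a median of 201 bp and a median q of 0.00264. In the decile of the combined list with the lowest q, 98.7% of peaks were found in both replicates. The combined list was called on the merged reads of the same 2 libraries, so these shares are not an independent measure of reproducibility. The peaks are neighbours on the same chromosomes and come from 2 libraries, so these p-values describe the libraries and not a population of animals.

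The 20 combined peaks with the lowest q, the rule set for naming regions, each overlapped a peak in both replicate lists. The first was on chromosome II, from 5333759 to 5340189 (6431 bp, q = 2.38e-210), and the second on chromosome I, from 9378709 to 9384130 (5422 bp, q = 2.17e-188). The next 5 were all on the X chromosome, at 8035897 to 8036965 (q = 3.08e-167), 16929180 to 16931962 (q = 3.09e-166), 2996335 to 2997559 (q = 5.48e-162), 14525269 to 14526638 (q = 1.62e-145) and 1453795 to 1455006 (q = 7.8e-145). In all, 11 of the 20 lay on X, 4 on II, 2 on I, 2 on IV, 1 on V and 0 on III. The other X regions among them were at 11093673 to 11094486, 4208504 to 4209761, 6296098 to 6297035, 12362688 to 12363581, 13700445 to 13701126 and 9465320 to 9466250. The remaining regions on autosomes were at II 11634799 to 11637892, II 5543258 to 5544425, II 9112586 to 9113990, I 7079167 to 7086168, IV 8431407 to 8433183, IV 14032552 to 14034627 and V 6226715 to 6229968. Widths in this group ran from 682 to 7002 bp, and 15 of the 20 exceeded 1000 bp. Among the 20 lowest q of each replicate list, 12 in replicate 1 and 11 in replicate 2 were on X. The q values are the authors' own, and genes at these positions were not assigned, since the gene table at hand belongs to another build (WBcel235).

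**Figure D1:**
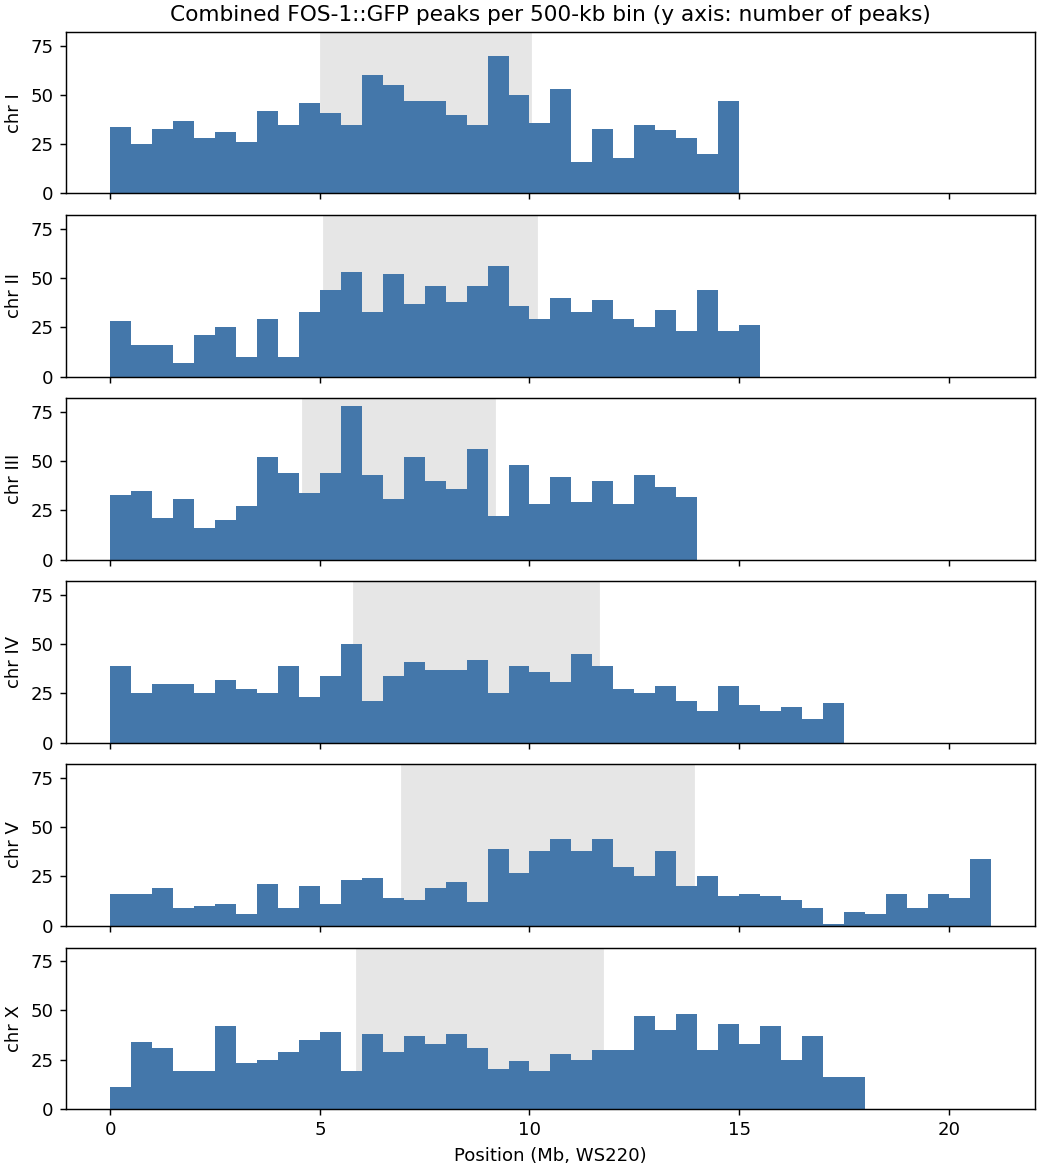
Number of combined FOS-1::GFP peaks in each 500-kb bin (y axis) along the 6 nuclear chromosomes (x axis, position in Mb, WS220). The grey band is the central part of each chromosome, from 33.3% to 66.7% of its length, which held 50.1% of the peaks on V and 31.9% of those on X.

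Called peaks were unevenly spread over the chromosomes. In the combined list, chromosome III carried 75.7 peaks per Mb, chromosome I 75.3, II 64.3, X 61.5, IV 59.4 and V 38.9. Chromosome V was the sparsest chromosome in each of the 3 lists, with 814 combined peaks, or 13.4% of peaks on 20.9% of the length (exact binomial test, Benjamini-Hochberg adjusted over 6 chromosomes, p = 1.87e-51). Chromosome III was above its length share in each list, with 17.1% of combined peaks on 13.8% of the length (adjusted p = 4.4e-13, exact binomial test). Chromosome I had 18.6% of combined peaks on 15.05% of the length (adjusted p = 1.13e-13, exact binomial test), but 15.3% of replicate 1 peaks, where the call was lost (adjusted p = 0.613, exact binomial test), and 12.5% of replicate 2 peaks, below its length share (adjusted p = 0.00183, exact binomial test). Chromosome II, with 15.2% of the length, was not called in the combined list (981 peaks, adjusted p = 0.0997, exact binomial test) but lay above its share in replicate 1 (17.5%, adjusted p = 0.000209, exact binomial test) and replicate 2 (19.3%, adjusted p = 2.55e-06, exact binomial test). Of the combined peaks, 46.7% on I and 50.5% on V overlapped no peak of either replicate, against 28.5% to 32.1% on the other chromosomes. The combined densities of I and V thus rested more on peaks that neither replicate list held. The tests by chromosome other than X were added after the data were seen. These binomial tests, and those of X below, treat peaks as independent. Neighbouring peaks cluster, so the p-values may be too small. Chromosome lengths were taken as the end of the last peak on each chromosome in any list.

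The X chromosome held 1085 combined peaks, 17.8% of the list (exact 95% interval 16.8 to 18.8), against 17.6% of the length, and no departure was detected (exact binomial p = 0.712, two-sided). This value depended on the list and on the chromosomes it was set against. X held 18.8% of replicate 1 peaks (exact binomial p = 0.0428) and 19.4% of replicate 2 peaks (exact binomial p = 0.0365), both above the length share. With chromosomes I and V left out, X lay below its 27.5% share of the remaining length in all 3 lists, at 26.2% in the combined list (exact binomial p = 0.0557), 25.3% in replicate 1 (exact binomial p = 0.0062) and 24.6% in replicate 2 (exact binomial p = 0.0101).

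**Figure D2:**
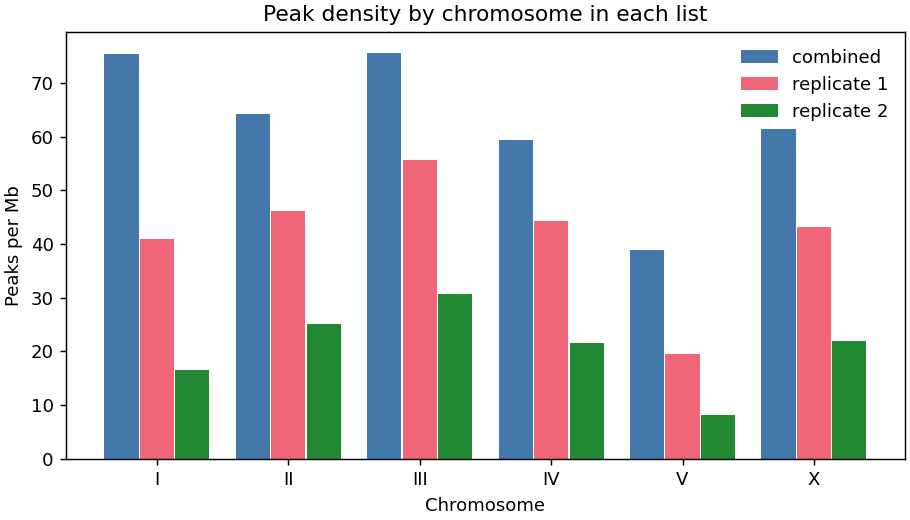
Peaks per Mb (y axis) on each nuclear chromosome (x axis) in the combined list, the replicate 1 list and the replicate 2 list, as bars. Chromosome V is the lowest in each list, at 38.9, 19.5 and 8.13 peaks per Mb, and chromosome I is close to III in the combined list (75.3 and 75.7) but below it in replicate 1 (41.0 and 55.7) and replicate 2 (16.46 and 30.72).

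Autosomal peaks were concentrated toward the middle of the chromosomes, which in this species are gene-dense and recombine less than the arms. Of 5010 combined peaks on autosomes, 2158 (43.1%, exact 95% interval 41.7 to 44.5) had their midpoint in the central part, between 33.3% and 66.7% of the chromosome's length, against 33.3% of positions (exact binomial p = 1.35e-46, two-sided). The share was 50.1% on V, 44.95% on II, 42.8% on I, 39.9% on IV and 39.3% on III, and in the combined list the lower end of the exact interval was above 33.3% on each of these autosomes. On X the share of combined peaks was 31.9% (29.1 to 34.8). In the replicate 2 list the interval on IV included 33.3% (35.8%, 30.97 to 40.88). After peaks no more than 2000 bp apart had been joined, which lowers the dependence between neighbours, the autosomal share was 41.0%.

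Combined peaks without a counterpart in either replicate were concentrated on chromosomes I and V, a comparison added after the data were seen. On chromosome V, 411 of 814 combined peaks (50.5%) overlapped no peak of either replicate, and on chromosome I 530 of 1135 (46.7%). The shares were 29.2% on II, 28.5% on III, 29.7% on IV and 32.1% on X. Together this was 48.3% on I and V against 29.9% on the other 4, and within deciles of the combined list ranked by q the Mantel-Haenszel odds ratio was 5.98 (permutation p = 0.001, two-sided, the smallest that 1000 resamples can give). I and V were chosen for their high shares, and the permutation treats neighbouring peaks as independent. This p therefore does not measure how much whole chromosomes differ by chance. Replicate 1 had 0.544 peaks for each combined peak on I and 0.50 on V, against 0.70 to 0.747 on the other chromosomes.

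**Figure D3:**
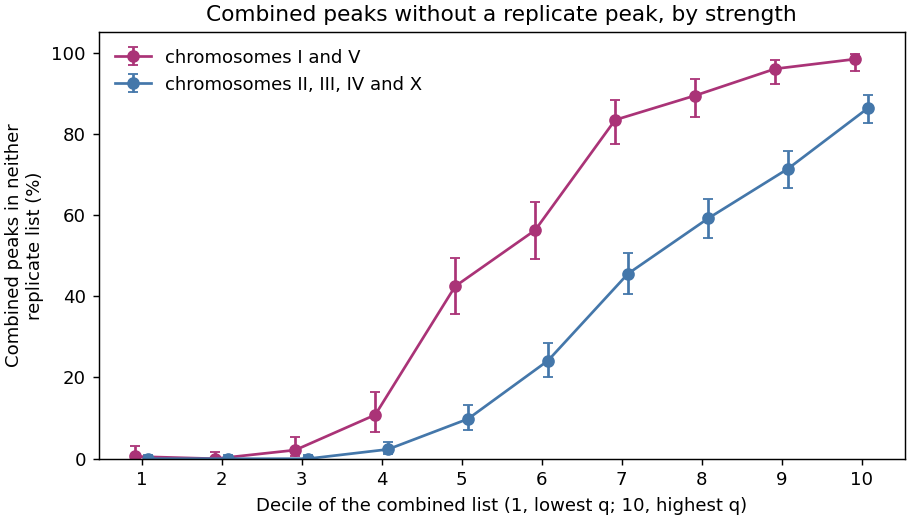
Share of combined peaks that overlapped no peak of either replicate list (y axis, percent, with exact 95% intervals) by decile of the combined list ranked by q (x axis, lowest q first), for chromosomes I and V together and for the other 4 chromosomes together. In decile 5 the shares were 42.5% on I and V and 9.80% on the others.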

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

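Alternatives that join neighbouring peaks, leave out narrow peaks, leave out chromosomes or move intervals locally, and all those of the strongest X peaks and of combined peaks without a replicate counterpart, were chosen after the data were seen. Of 49 alternative values, 37 kept their direction and their side of the threshold or, where there was no test, stayed close to the main value (a count within 1.5 times of it, the X share of covered bases within its interval). This held for all 6 alternatives of the replicate overlap (73.9% to 94.6%), both of the strength of shared peaks, all 11 of the central part of autosomes (39.9% to 44.4%), 5 of 6 of the X share of the 100 strongest peaks and all 5 of the combined-only share on I and V. The number of peaks moved from 6095 to between 1987 and 4032 with one replicate list alone, to 3048 among the 50% of peaks with the lowest q, by construction, and to 1776 when both replicates were required. The X share of all peaks was 18.8% to 19.4% with one replicate list alone. Without adjustment both were past the threshold, and after adjustment over 6 chromosomes only replicate 2 was. The X share fell below the length share among the 50% of peaks with the lowest q (16.9%) and with chromosomes I and V left out of the combined (26.2%), replicate 1 (25.3%) and replicate 2 (24.6%) lists. Shares within a list are tied to each other, so the low share of V raises that of X. No other cause of these shifts was tested. The X share of ranks 21 to 100 was 25%, no longer past the threshold (Fisher's exact p = 0.103). The smallest distance between X peaks was 0.0432 Mb among the 50 strongest peaks, no longer past the threshold (permutation p = 0.328).

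No paired analysis was possible because the ChIP and input libraries enter the peak lists only through the authors' calling, and no test compared the groups library by library. Other settings fixed in advance for promoters, gene lists, non-coding RNA genes, motifs and the transgene's genes were not run, since these results need the genome or annotation of the build. The effect of depth was not tested. ChIP replicate 2 had 2961912 uniquely mapped reads and replicate 1 had 3763795, and a combined peak missing from a replicate list was not called there, which does not show that it was unbound.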

Other observations

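All tests in this part were chosen after the lists had been seen, although the values in the 2-Mb segments and the replicate peaks without a combined peak by chromosome had not been seen when those tests were chosen. In the combined list 28.3% of gaps between neighbouring peaks were 2000 bp or shorter, against 13.97% on average for peaks placed at random on the same chromosomes and 15.2% for peaks placed at random within their own 500-kb bins, which keeps the regional density (permutation p = 0.001 for both, the smallest that 1000 placements can give). Splitting of a site by the peak caller was not separated from neighbouring sites, and the combined peak at I 7079167 to 7086168 overlapped 2 peaks of replicate 1 and 4 of replicate 2. Joining such neighbours left 4372 regions. The densest 100-kb windows of the combined list held 23 peaks each, on chromosome II from 6.8 to 6.9 Mb (22 peaks in replicate 1 and 9 in replicate 2) and on chromosome V from 20.7 to 20.8 Mb (14 and 3). The window of chromosome II that holds the strongest peak, from 5.3 to 5.4 Mb, had 20 combined peaks, 22 in replicate 1 and 13 in replicate 2. Of 1004 such windows, 47 held no combined peak.

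The X chromosome held 31 of the 100 combined peaks with the lowest q (31%, exact 95% interval 22.1 to 41.0) and 17.6% of the rest (Fisher's exact p = 0.00133, two-sided), with 30 of the top 100 in replicate 1 and 29 in replicate 2, but the 20 strongest, 11 of them on X, had prompted the test, and ranks 21 to 100 alone held 20 X peaks of 80 (Fisher's exact p = 0.103). Splitting of single sites is argued against, since X held 31% of the 100 strongest regions after neighbours had been joined. A scale factor that lifts every peak on X stays open. X held 19.51% (16.44 to 22.88) of the first decile in the combined list, 24.3% (20.2 to 28.7) in replicate 1 and 26.6% (20.6 to 33.3) in replicate 2. Its share of the second decile of the combined list was 12.32% (exact interval 9.81 to 15.2), the lowest of the 10 deciles and below its 17.6% of the length. In replicates 1 and 2 the share of that decile was 13.9% (10.7 to 17.7) and 19.1% (13.9 to 25.3). In decile 8 of the combined list X held 134 of the 609 peaks (18.8 to 25.5%). The 11 X peaks among the 20 strongest were spread along the chromosome with a smallest distance of 0.825 Mb, against a median of 0.0935 Mb for X peaks drawn at random (permutation p = 0.00103), but the distance was 0.455 Mb in the replicate 2 list alone (permutation p = 0.0345), 0.426 Mb in the replicate 1 list alone (permutation p = 0.0225) and 0.0432 Mb in the top 50, where the call was lost (permutation p = 0.328). A candidate explanation is that these are sites where the dosage compensation complex is recruited to X, which are scattered along that chromosome, but it stays open, since their positions were not used here and no other factor's binding was compared.

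Combined peaks with no replicate counterpart were enriched on chromosomes I and V. Higher combined q values on those chromosomes are argued against as the whole cause: the odds ratio was 2.19 over all peaks and 5.98 within deciles of q. Weaker read signal on I and V stays open, because the ranking rests on the combined q itself and no read-level signal was used. A few unusual regions are argued against as well: in 2-Mb segments, the ratio of such peaks to the number predicted from q on the other chromosomes was 1.37 or higher in all 19 segments of I and V and at most 1.27 in the 33 segments of the others. A calling threshold for whole chromosomes that was looser in the combined than in the replicate lists on I and V may account for this: it needs fewer replicate peaks without a combined peak there, and these were 33 of 1025 in replicate 1 against 175 of 3007 elsewhere (odds ratio 0.538, Fisher's exact p = 0.00101), with 1 of 418 against 22 of 1569 in replicate 2 (Fisher's exact p = 0.0666). Any cause that gives more combined peaks per replicate peak on I and V could also lower these counts. They therefore do not single out a threshold. How PeakSeq was scaled on each chromosome is not given in the sources used here, and no biological explanation was tested, since both replicates are of 1 group.

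The widest combined peak spanned 36723 bp (36.7 kb) on chromosome V, from 5985705 to 6022427 (q = 7.73e-29), 5.24-fold wider than the next. Inside it lay 0 peaks of either replicate, while all 29 other combined peaks of 2000 bp or wider, and all 203 others with a lower q, overlapped a replicate peak. Merged ordinary sites would leave replicate peaks there only if the replicate calls covered the block. Whether they did is not known, so the merging of several sites stays open. Extra copies of the transgene could give a block of this width, and fos-1 lies on chromosome V in the WBcel235 gene table. Whether the block holds fos-1 was not determined, because the gene's position in the WS220 build was not used here. Extra copies thus cannot be told apart from other causes on V, and the absence from both replicate lists was not explained.

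The region at the right end of chromosome I, from 15064000 to 15067635 in replicate 1 (q = 6.38e-19) and from 15063997 to 15067644 in replicate 2 (q = 2.7e-43), ranked 7 by q in replicate 2 and had no combined peak. It was 1 of 5 regions found in both replicates and absent from the combined list, which otherwise held 94.8% of replicate 1 peaks and 98.8% of replicate 2 peaks.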
